A study of Gallus gallus with 3 samples.

How the data were processed

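RNA from the jejunal mucosa of chickens was sequenced in pools of 4 hens, and 3 pools of the thermoneutral control arm were analysed here, numbered 1 to 3 as in their labels. Per the labels' protocols, RNA was extracted with a column kit, messenger RNA was isolated by poly(A) selection or ribosomal RNA removal, and random-primed cDNA libraries were amplified by PCR. The submitters' processing notes name cutadapt 1.9.1, HISAT2 2.0.1, HTSeq 0.6.1 and DESeq2, for which no version is given, and the chicken build GRCg6a. The role and order of these tools and the gene annotation are not given in the sources used here. Whether reads were counted by strand is not given either, so overlapping genes and near-identical gene copies carry that uncertainty.

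Per the file headers, the authors deposited FPKM values, read fragments scaled to transcript length and to the mapped fragments of the library, for each pool. The deposited table has 15676 rows, of which 15675 have FPKM and 1 has neither a symbol nor FPKM. FPKM are scaled for length and library size and given to 2 decimals. They were used as deposited, so a gene that takes a large share of a library lowers the others. The sums of FPKM were 939772, 948742 and 936084 in pools 1, 2 and 3. A further 6 columns of values match no sample in the labels and were not used in any analysis. In 19 rows a spreadsheet had turned the gene symbol into a date, and these rows could not be named.

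Per the file headers, the authors also deposited a read count for each pool, which is best described as an estimated count, since 86.8% to 86.9% of the values were whole numbers within 1e-06. These counts did not follow the FPKM of the same row. Pearson's r across 15675 rows of log2(count + 1) and log2(FPKM + 1) was 0.009, 0.006 and 0.005 in pools 1, 2 and 3. FABP1, at 20545.54 FPKM in pool 1, had a count of 80 there, and POC1B, at 7.63 FPKM, had 104371. The counts were therefore used for no expression value. They and their sums entered only the checks of how counts and FPKM relate, 1 of which takes the sums as library totals. FPKM keep steps that depend on depth, but ratios of low FPKM between pools showed no dominant step, with at most 65 of 1374 genes in the fullest bin, so relative depth could not be read either. No interval for counting error is given, and genes near 1 FPKM are the least precise.

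All 3 libraries belong to 1 group, so no comparison between groups was made, no count model was fitted and results are values with their spread. Values were transformed as log2(FPKM + 1), which understates differences of genes with low FPKM. Genes with a mean of at least 1 FPKM entered the correlations, the spread and the lists. Before the data were examined, 39 lists were fixed, 14 of cell type markers and 25 of pathways and functions, with 24 pairs of related genes. Of 734 listed symbols, 627 matched by symbol and 7 by a synonym in the RefSeq gene table of assembly GRCg7b, from which no coordinates were taken. Another 4 synonym matches were excluded after seeing them because they pointed to other genes. A list with at least 5 members was set against 10000 random lists of the same size. For its level these were drawn from all genes with a mean of at least 1 FPKM, and for its shift in a pool they were matched in 20 bins of mean expression. A shift was called when its percentile was under 0.5 or over 99.5. The step was tested on simulated data with the real gene means, where it called 20 of 20 lists of 12 genes raised by 1 on the log2 scale, 20 of 20 lowered, and 1 of 200 unchanged lists. Simulated genes varied independently with 1 common SD, which genes of a real list do not. These rates therefore do not give the error or the power for the lists here, nor for shifts under 1. Pairs were tested with an exact two-sided sign-flip permutation test, and 2 of the 24 pairs were left out, 1 for an unmatched gene and 1 because both genes were under 1 FPKM.

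Named genes were chosen by a rule fixed before the data were examined: the 10 with the highest mean FPKM, up to 4 with the highest mean in each list, the 5 with the widest range between pools among those with a mean of at least 5 FPKM, and both genes of each pair. Other genes, such as APOB, APOC3, MEP1A, DES, HSPB7, DNAJA1, SERPINH1, USP18, CMPK2, BF1, IL6, IL1B, ALPI and SLC10A2, were members of the fixed lists named after their values were seen. Some genes that the rule selects, and 1 pair that is counted, are not reported here by name. Alternatives were another pseudocount of 0.1, other minimum values, values rescaled to an equal sum or by the median ratio, a mean over members, and each pool left out in turn. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.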

Results

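The jejunal mucosa of Leuang Hang Kao breeder hens, a heat-adapted chicken, was profiled by RNA sequencing. The study set hens of 28 weeks kept at 23 °C against hens exposed to 36 °C for 6 h, with 25 hens per arm. RNA from 12 hens per arm was combined into 3 pools of 4 hens each. The values below come from the 3 pools of the thermoneutral arm, called control pools 1, 2 and 3, and the heated arm was not analysed here. What follows is therefore a description of the resting mucosa and of how far pools of the same group differed, the error against which a response to heat would be held. Values are FPKM as mean ± SD over the 3 pools (n = 3), and the SD is the spread between pools of RNA, not between single hens. The sequencing depth of the libraries is unknown. Between 11217 and 11810 genes reached 1 FPKM in a pool, 11016 did so in all 3, and 3658 of 15675 did so in none.

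The most abundant genes of the control mucosa included 3 of lipid absorption and 3 of the ribosome. By mean over the pools, the most abundant transcript was IGLL1, an immunoglobulin light chain gene, at 18988 ± 7305 FPKM. Its rank rests on pool 3, at 27244.08. In pools 1 and 2 it was at 13360.14 and 16361.05, below FABP1 at 20545.54 and 20224.86. FABP1 and FABP2, cytosolic fatty acid carriers of the enterocyte, stood at 15080 ± 9191 and 7718 ± 2541, and APOA1, the main apolipoprotein of high-density lipoprotein, at 14656 ± 7775. FTH1, the ferritin heavy chain that stores iron, reached 11151 ± 1630, and PLA2G2E, a secreted phospholipase, 10162 ± 4503. RPL37A, RPL27 and RPS12, proteins of the ribosome, reached 10021 ± 821, 7547 ± 402 and 7130 ± 726. The galectin LGALS2 was at 6550 ± 23.5, the smallest SD among these genes. The 10 most abundant genes held 11.6% ± 0.767 of the summed FPKM, the first 50 held 30.3% ± 0.293 and the first 100 held 44.0% ± 0.537.

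Genes of lipid absorption and brush border digestion were abundant as groups. The median member of the lipid absorption list had a level equal to 95.37 FPKM, above every one of 10000 random lists of the same size, and that of the brush border digestive enzymes 78.57 FPKM, at percentile 99.99. The retinol carrier RBP2 reached 6366 ± 2000 FPKM. In the enzyme list, the aminopeptidase ANPEP was at 682 ± 103, maltase-glucoamylase MGAM at 438 ± 108 and sucrase-isomaltase SI at 279 ± 73.4. PEPD, a cytosolic dipeptidase that the list also holds, was at 451 ± 80.4. Intestinal alkaline phosphatase ALPI was at 1.07 ± 0.126. CALB1, the calcium-binding calbindin, reached 2954 ± 504. Of the sugar transporters, the sodium-coupled SLC5A1 was at 710 ± 181, against 32.6 ± 13.6 for the fructose transporter SLC2A5 and 25.8 ± 14.6 for the basolateral SLC2A2. Leading amino acid carriers were SLC1A1 at 121 ± 23.4, SLC7A6 at 117 ± 10.9, SLC7A9 at 111 ± 45.6 and SLC3A1 at 106 ± 28.5. The carbohydrate, amino acid and peptide, and mineral and water transporter lists lay at percentiles 64.22, 84.55 and 96.22 of random lists.

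Transcripts of ribosomal proteins and of oxidative phosphorylation, glycolysis and antioxidant genes were also abundant. The 31 ribosomal proteins had a median level of 2430.76 FPKM and the 19 measured subunits of oxidative phosphorylation 320.37 FPKM, both above all random lists, with COX4I1 of cytochrome c oxidase at 2403 ± 82.5. Glycolysis and hypoxia genes lay at percentile 99.99, with GAPDH at 2007 ± 262. Antioxidant genes had a median level of 124.09 FPKM, with the peroxidase PRDX1 at 1727 ± 161 and the redox protein TXN at 926 ± 112. Fatty acid oxidation genes, led by HADH at 684 ± 89.6, and cholesterol synthesis genes, led by MSMO1 at 295 ± 91.0, lay at percentiles 99.27 and 99.02, and fatty acid synthesis genes at 42.20. None of the 26 symbols listed for mitochondrially encoded genes was matched, so these were not analysed here.

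Chaperones were abundant in hens that had not been heated. The 30 measured heat shock proteins and cytosolic chaperones had a median level of 38.85 FPKM, at percentile 99.92, and the 22 endoplasmic reticulum stress genes one of 64.11 FPKM, above all random lists. The constitutive HSPA8 stood at 1089 ± 38.6 FPKM and HSPE1, the mitochondrial co-chaperonin, at 999 ± 180. HSP90AA1 was at 257 ± 21.6 and the mitochondrial chaperonin HSPD1 at 221 ± 35.6. HSPA2 was at 51.7 ± 25.6. Among the endoplasmic reticulum stress genes, the lectin chaperone CALR reached 1396 ± 92.3, the stress transcription factor ATF4 802 ± 45.5, MANF 529 ± 47.9 and PDIA3 488 ± 43.0. The heat shock factors were low by comparison, with HSF3, a factor known from birds, at 13.2 ± 0.774, HSF1 at 6.87 ± 0.259 and HSF2 at 6.28 ± 1.08. HSBP1, which binds HSF1, was at 83.9 ± 6.57.

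Among the cell type lists, enterocyte markers had the highest level, and markers of lymphocytes and deeper tissue were also detected. Levels of chosen markers do not measure the amounts of cell types. Enterocyte markers had a median level of 930.01 FPKM, above all random lists, enteroendocrine markers 75.99 FPKM at percentile 99.92, and goblet markers 45.90 FPKM at percentile 98.15. The enteroendocrine level was 5.02 FPKM, at percentile 36.44, when members under 1 FPKM were kept, and at percentile 92.24 as a mean over members. The goblet protein AGR2 was at 1502 ± 218 and the mucin MUC2 at 188 ± 45.7, and the hormone genes GIP, NTS and GCG were at 538 ± 92.5, 217 ± 36.0 and 143 ± 40.6. Crypt stem and proliferating markers lay at percentile 68.52, T and NK lymphocyte markers at 76.33, B and plasma cell markers at 44.23, macrophage and dendritic markers at 44.28 and heterophil and mast markers at 1.69. The T cell receptor component CD3D was at 482 ± 59.8, the granzyme GZMA at 186 ± 12.8 and JCHAIN, which joins secreted antibodies, at 2239 ± 1090. Smooth muscle markers were at percentile 99.35, fibroblast and stroma markers at 98.05 and endothelial markers at 5.05. The haemoglobin genes HBA1 and HBBA were at 61.2 ± 28.3 and 52.9 ± 25.2, and the neuronal marker UCHL1 at 5.32 ± 0.772. Of 11 measured exocrine pancreas markers, 1, AMY1A, reached a mean of 1 FPKM.

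Among defence genes, those of antigen presentation were the most abundant as a group. Antigen presentation genes had a median level of 167.76 FPKM, above all random lists, led by B2M, the light chain of class I molecules, at 4590 ± 698 and by the class II invariant chain CD74 at 3008 ± 67.0. Antimicrobial and mucosal defence genes also lay above all random lists, with the antibody transporter PIGR at 1603 ± 155 and the liver and gut peptide LEAP2 at 426 ± 156. This held for the 10 of 15 measured members with a mean of at least 1 FPKM, and over all 15 the median level was 14.89 FPKM, at percentile 90.67. Interferon stimulated genes lay at percentile 94.95. The inflammatory list, with a median level of 5.15 FPKM at percentile 0.43, was the only list in the lower 0.5% of random lists, but it lay at percentile 8.20 without the filter on low values, 40.08 over genes of at least 5 FPKM and 2.06 without pool 3. IL6 was at 0.267 ± 0.0513 FPKM, IL1B at 2.43 ± 0.389 and the chemokine CCL20 at 30.0 ± 4.62. Tight and adherens junction genes lay at percentile 99.89, or 99.34 as a mean over members, with CLDN2 at 411 ± 38.5. Apoptosis and autophagy genes lay at 99.00, immediate early genes and stress kinases at 92.35, circadian clock genes at 54.16, and glucocorticoid and thyroid signalling genes at 45.78. In all, 13 of 34 lists with at least 5 members at a mean of 1 FPKM or more lay in the upper 0.5% of random lists and 1 in the lower 0.5%, as a description of these libraries.

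**Figure D1:**
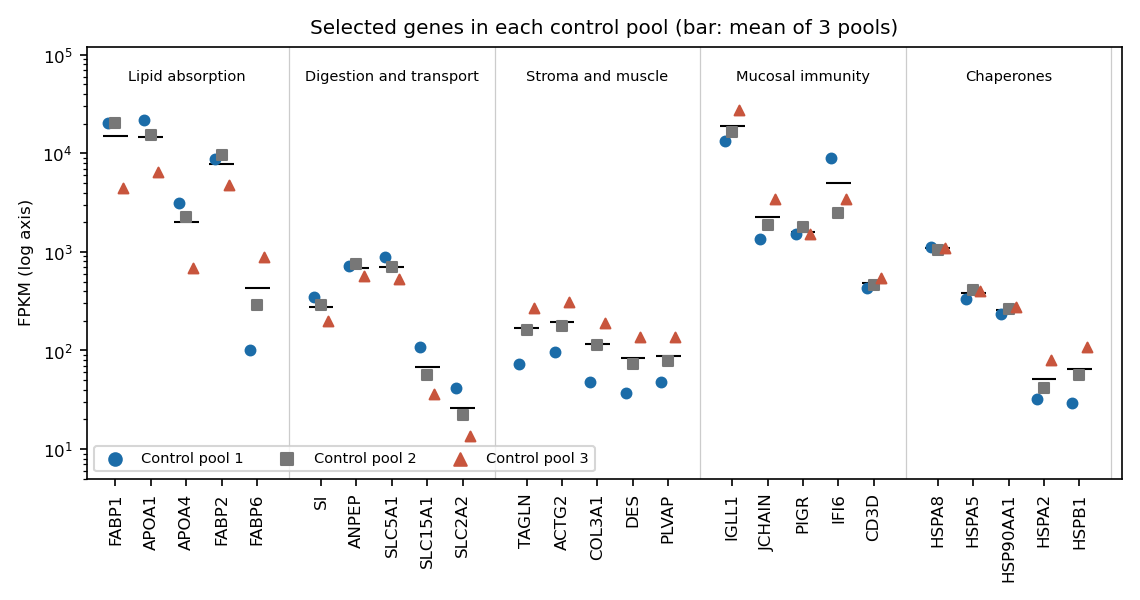
FPKM on a log axis of 25 genes from 5 groups, with 1 symbol per control pool and a bar at the mean of the 3 pools. FABP1 was at 20545.54, 20224.86 and 4468.83 FPKM in pools 1, 2 and 3, and TAGLN at 73.46, 162.74 and 270.59, while HSPA8 lay between 1045.89 and 1119.72.

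Within pools, most of the measured gene pairs kept the same order. HSPA8 exceeded its endoplasmic reticulum counterpart HSPA5 by 1.52 ± 0.21 and HSPA2 by 4.48 ± 0.67 on the log2(FPKM + 1) scale, and HSP90AB1 was below HSP90AA1, with a difference of -4.35 ± 0.21. The peptide transporter SLC15A1 exceeded SLC15A2, which was at 0.0600 ± 0.0529 FPKM, by 5.87 ± 0.72, SLC5A1 exceeded SLC2A2 by 4.84 ± 0.42, ANPEP exceeded DPP4 by 2.92 ± 0.08, and APOA1 exceeded APOA4 by 2.94 ± 0.26. Among claudins, CLDN3 exceeded CLDN5 by 5.53 ± 0.21, and CLDN1 minus CLDN3 was -5.25 ± 0.16. OCLN exceeded TJP1 by 1.37 ± 0.46, NFE2L2, the antioxidant transcription factor, exceeded its inhibitor KEAP1 by 3.20 ± 0.17, and SOD1 exceeded SOD2 by 1.26 ± 0.13. FABP2 exceeded FABP6, the bile acid carrier, by 4.63 ± 2.03. SLC2A1 was below SLC2A5, with a difference of -1.43 ± 1.26. Differences under 1 in size but in one direction were found for SLC2A2 minus SLC2A5, at -0.38 ± 0.24, SI minus MGAM, at -0.65 ± 0.10, and CD8A minus CD4, at 0.58 ± 0.23. The order differed between pools for FABP1 and FABP2 (0.73 ± 0.74), GPX1 and GPX4 (-0.50 ± 0.64), PIGR and JCHAIN (-0.38 ± 0.72) and HSF1 and HSF2 (0.12 ± 0.26). Thus 18 of 22 measured pairs had the same direction in all 3 pools, and 14 had a mean difference over 1 in size. The share for pairs of unrelated genes was not computed, so the count shows no trait particular to related genes. The exact sign-flip permutation test, two-sided, can give no p below 0.25 with 3 pools, and its smallest Benjamini-Hochberg adjusted p over the 22 pairs was 0.306, so no pair could pass a threshold. Members of gene families can share reads, and the direction within such pairs carries that uncertainty.

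The 3 control pools were alike across genes, and differed in a limited set. Pearson's r of log2(FPKM + 1) across 11570 genes, which are not independent replicates, was 0.987 for pools 1 and 2, 0.984 for pools 2 and 3 and 0.974 for pools 1 and 3. Spearman's rho was 0.984, 0.981 and 0.968. The median SD between pools was 0.17 on this scale. In 817 genes, 7.06% of those with a mean of at least 1 FPKM, the highest and lowest pools differed by more than 1. Of these, 567 were highest in pool 3 and 563 lowest in pool 1. The number was 1374 with a pseudocount of 0.1, 464 over genes of at least 5 FPKM, and 206 and 185 without pools 1 and 3. The genes with the widest range among those with a mean of at least 5 FPKM were of mixed kinds. MSMB, a secreted protein, was at 484.75, 48.76 and 622.30 FPKM in pools 1, 2 and 3. The unnamed gene LOC107052494 was at 125.40, 2.42 and 127.57, and LOC107050181 at 296.96, 304.61 and 26.16. The beta-defensin AvBD10 was at 19.38 in pool 2 and listed at 0 in the others, and LOC112532770 was at 18.72 in pool 3 and listed at 0 in the others.

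Genes of tissue below the epithelium differed most between pools. For each pool, a list's shift is the median over its members of log2(FPKM + 1) minus the mean of the other pools. Smooth muscle markers had shifts of -1.32, 0.14 and 1.21 in pools 1, 2 and 3, and all 12 were highest in pool 3 and lowest in pool 1. The contractile genes ACTG2 and TAGLN were at 96.84 and 73.46 FPKM in pool 1 and at 309.18 and 270.59 in pool 3, and DES, the muscle intermediate filament, was at 37.09 and 138.13. Fibroblast and stroma markers had shifts of -1.09, 0.03 and 0.92, again with all 12 highest in pool 3 and lowest in pool 1. COL3A1, a fibrillar collagen, was at 47.64 and 189.60 FPKM in these pools, and SPARC at 52.69 and 152.65. Endothelial markers had shifts of -1.01, -0.05 and 0.95, with PLVAP at 47.71 FPKM in pool 1 and 137.34 in pool 3. The shifts in pools 1 and 3 lay in the upper or lower 0.5% of 10000 random lists matched on expression, the criterion used for every list below, while those in pool 2 did not.

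Enterocyte genes ran the other way, with the widest differences among those of lipid handling. Enterocyte markers had shifts of 0.36, 0.25 and -0.87 in pools 1, 2 and 3, and the lipid absorption list 0.38, 0.30 and -0.75, with 23 of its 27 members lowest in pool 3. Without pool 3, the shifts of these lists in pool 1 were 0.14 and 0.08, and neither met the criterion. FABP1 was at 20545.54 FPKM in pool 1 and 4468.83 in pool 3, APOA4 at 3155.46 and 683.99, APOB, the structural protein of lipoprotein particles, at 195.02 and 62.18, and APOC3 at 118.35 and 12.82. FABP6 was an exception, at 100.68, 291.55 and 897.59 FPKM in pools 1, 2 and 3, as was SLC10A2, the apical bile acid transporter, at 2.24, 2.06 and 6.84. The brush border enzyme list had shifts of 0.52, 0.21 and -0.52. Of its members, 16 of 17 were lowest in pool 3, including MEP1A, a subunit of the protease meprin, at 170.37 FPKM in pool 1 and 49.30 in pool 3. Cholesterol synthesis, at -0.42 in pool 3, fatty acid oxidation, at -0.39, mineral and water transport, at -0.28, and carbohydrate transporters, at -0.26, were also low there. In pool 1, cholesterol synthesis, at 0.35, mineral and water transport, at 0.29, and carbohydrate transporters, at 0.18, met the criterion on the higher side. The mineral and carbohydrate shifts there were both 0.07 without pool 3, and 0.07 and 0.14 as a mean over members, and none of these met it. All 7 of these lists met the criterion in pool 3, where stromal and muscle markers were highest. As a mean over members, mineral and water transport, at -0.16, and carbohydrate transporters, at -0.23, fell just short of it there. In pool 2, the shifts of the enterocyte, lipid absorption and brush border lists met it only through the contrast with pool 3: without that pool they were -0.14, -0.08 and -0.17, and the last lay at percentile 0.10, past the criterion on the lower side. The enterocyte calls also rest on genes shared with other lists: over the members found in no other list its shifts were 0.25, 0.08 and -0.34, and none met the criterion.

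Crypt, chaperone and ribosomal genes were lowest in pool 1. Crypt stem and proliferating markers had shifts of -0.62, 0.20 and 0.50 in pools 1, 2 and 3, and all 11 were lowest in pool 1. The stem cell zone gene OLFM4 was at 54.66, 129.22 and 119.40 FPKM, and the cell cycle genes CDK1 and PCNA were at 126.08 and 35.41 in pool 1 against 198.68 and 72.43 in pool 3. Without pool 1, the shift of the list was -0.15 in pool 2 and 0.15 in pool 3, and neither met the criterion. Heat shock proteins and cytosolic chaperones had shifts of -0.27, -0.02 and 0.29, with 24 of 30 lowest in pool 1 and 24 highest in pool 3. Smooth muscle and fibroblast markers were likewise lowest in pool 1 and highest in pool 3, with shifts of 1.21 and 0.92 in pool 3. The widest ranges in this list belonged to HSPB7, with a range of 1.93 on the log2 scale, HSPB1, at 29.37 FPKM in pool 1 and 108.66 in pool 3, SERPINH1, the collagen chaperone, at 19.19 and 51.53, and HSPA2, at 32.42 and 80.72. HSPA8, at 1119.72 and 1102.59, and DNAJA1, at 72.18 and 80.00, differed little. Endoplasmic reticulum stress genes were at -0.24 in pool 1. Ribosomal proteins had shifts of -0.23, 0.08 and 0.16, with all 31 lowest in pool 1 and a shift of 0.04 in pool 3 without pool 1, and T and NK lymphocyte markers were at -0.32 in pool 1. The endoplasmic reticulum stress and T and NK shifts in pool 1 were -0.17 and -0.29 as a mean over members. They were -0.24 and -0.35 without pool 2, and none of these met the criterion.

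Interferon and antigen presentation genes stood highest in pool 1. Interferon stimulated genes had shifts of 0.26, -0.20 and -0.10 in pools 1, 2 and 3, and 16 of 18 were highest in pool 1. IFI6, an interferon-induced membrane protein, was at 9052.93 FPKM in pool 1 against 2472.22 and 3431.91. USP18, which restrains interferon signalling, was at 43.27 against 16.53 and 20.87, OASL at 155.21 against 101.94 and 74.72, and CMPK2 at 37.19 against 19.94 and 20.71. The shifts in pools 1 and 2 met the criterion, but without pool 1 that in pool 2 was -0.10 and did not. Antigen presentation genes were at 0.28 in pool 1, or 0.10 without pool 2, which did not meet it, with 11 of 17 highest there, including the class I gene BF2 at 2807.63 FPKM against 2063.56 and 1835.25. BF1 was at 873.31 in pool 3 against 1540.62 and 1535.24.

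In all, 39 of 102 combinations of list and pool met the criterion, in 21 of 34 lists, where chance would give 1.02 if genes of a list varied independently. They do not, so the percentiles describe these libraries and are not p-values. The calls not given above were enteroendocrine markers at 0.25, fatty acid oxidation at 0.17, immediate early genes and stress kinases at -0.14 and glucocorticoid and thyroid signalling at -0.15, all in pool 2, and inflammatory genes at -0.04 in pool 3. In pool 2 without pool 3, fatty acid oxidation was at 0.03 and immediate early genes at -0.02. Glucocorticoid and thyroid signalling was at -0.03 over genes of at least 5 FPKM, and none of these met the criterion. The inflammatory shift was near 0 but low against its matched random lists, which had a median shift of 0.16 in pool 3. It was 0.09 over members with at least 5 FPKM. The goblet, B and plasma cell, macrophage and dendritic, heterophil and mast, antioxidant, junction, amino acid transporter, fatty acid synthesis, glycolysis, oxidative phosphorylation, antimicrobial, circadian clock, and apoptosis and autophagy lists met the criterion in no pool. The median shift of all genes was -0.10, 0.01 and 0.10 in pools 1, 2 and 3.

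**Figure D2:**
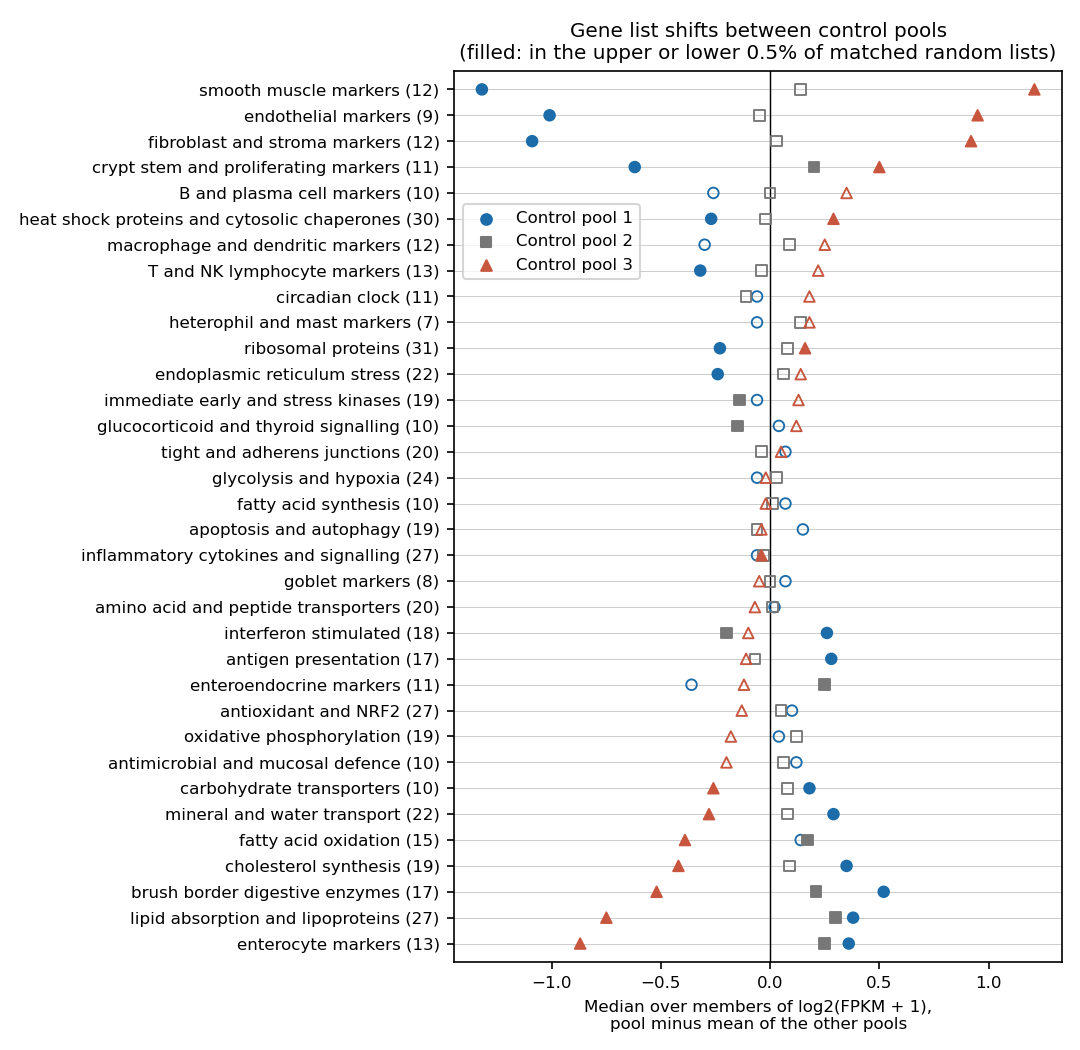
Shift of each of 34 gene lists in each control pool, as the median over members of log2(FPKM + 1) minus the mean of the other pools, with the number of members in brackets and filled symbols in the upper or lower 0.5% of matched random lists. Smooth muscle markers span -1.32 in pool 1 to 1.21 in pool 3, and enterocyte markers 0.36 to -0.87.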

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

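The list shifts with each pool left out, the correlation with each pool left out, and the use of members of a single list were chosen after seeing the data, and the other alternatives before. Of the 39 list calls, 37 kept direction and call when FPKM were rescaled to an equal sum, 37 with median ratio scaling, 38 with a pseudocount of 0.1, 36 over genes of at least 5 FPKM, 28 with a mean over members and 34 over members of a single list. With 1 pool left out, 16 of 23, 26 of 30 and 15 of 25 calls in the remaining pools were kept without pools 1, 2 and 3, and 24 to 28 were made. A mean over members ended the calls on mineral and water and on carbohydrate transport in pools 1 and 3, endoplasmic reticulum stress, T and NK and antigen presentation genes in pool 1, and crypt, immediate early and glucocorticoid genes in pool 2. Members of a single list ended the 3 enterocyte calls and the glucocorticoid call. The glucocorticoid call was also lost over genes of at least 5 FPKM, with median ratio scaling and with a pseudocount of 0.1, and the carbohydrate call in pool 1 over genes of at least 5 FPKM and rescaled. Leaving out pool 1 ended the calls on crypt and ribosomal genes in pool 3 and on interferon, immediate early and glucocorticoid genes in pool 2. Leaving out pool 2 ended those on endoplasmic reticulum stress, T and NK and antigen presentation genes in pool 1. Leaving out pool 3 ended those on enterocyte, lipid, carbohydrate and mineral genes in pool 1 and on fatty acid oxidation, immediate early and glucocorticoid genes in pool 2. The inflammatory call in pool 3 was lost with median ratio scaling, and its shift was 0.03 rescaled to an equal sum, 0.09 over genes of at least 5 FPKM, 0.05 as a mean, 0.02 over members of a single list and 0.04 to 0.07 with a pool left out, and the cause was not tested. The shifts in pool 2 ranged from -0.15 to 0.47 for crypt markers, -0.14 to 0.80 for enterocyte markers, -0.17 to 0.53 for brush border enzymes and -0.08 to 0.73 for lipid absorption, since pool 2 was then set against a single other pool. HSF1 minus HSF2 ranged from -0.02 to 0.22 and PIGR minus JCHAIN from -0.64 to 0.03 with a pool left out. With a pseudocount of 0.1, 3 pairs that hold a gene near or under 1 FPKM moved by more than their SD, SLC15A1 minus SLC15A2 to 8.62, CLDN1 minus CLDN3 to -6.01 and CLDN3 minus CLDN5 to 6.56. The mean correlation between pools was 0.988 without a filter on low values, and 0.974 to 0.987 for the pair left when a pool was removed. Genes with a range over 1 numbered 817, or 1374 with a pseudocount of 0.1, 464 over genes of at least 5 FPKM, and 206, 684 and 185 without pools 1, 2 and 3. The level calls numbered 14 to 18 over the alternatives against 14. Lost calls were enteroendocrine (percentile 36.44 without a filter, 92.24 as a mean), antimicrobial (90.67 without a filter), junction (99.34 as a mean) and inflammatory genes (8.20 without a filter, 40.08 over genes of at least 5 FPKM, 2.06 without pool 3). Detected genes numbered 11877 at 0.5 FPKM and 8060 at 5 FPKM, against 11016, the share of the top 10 genes ranged from 11.3% to 12.1%, and the median SD from 0.12 to 0.19. The planned comparison of fold changes was not run because the table used holds none, nor the share without mitochondrially encoded genes, of which none was matched. No paired comparison between groups was possible because all samples belong to 1 group.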

Other observations

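Further genes differed between control pools. Within the goblet list, CLCA1 was at 72.07, 147.75 and 30.67 FPKM in pools 1, 2 and 3 and FCGBP at 54.50, 29.68 and 20.09, while the goblet transcription factor SPDEF was at 31.95, 29.69 and 31.64. The haemoglobin gene HBA1 was at 28.64, 74.91 and 80.01 FPKM, and the B cell transcription factor PAX5 at 5.89, 1.27 and 2.55. The water channels AQP10 and AQP1 ran in opposite directions, at 17.84, 11.45 and 5.09 and at 0.73, 2.36 and 5.70 FPKM. GPX4, which protects membrane lipids from oxidation, was at 386.42, 527.27 and 217.13, while GPX1 varied little, with an SD of 0.789 around 250 FPKM. TCAP, a protein of striated muscle, was at 0.63, 12.86 and 2.58. These genes were chosen after their values were seen.

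All tests below except that of a more distal stretch of intestine were chosen after the result was seen, and the bootstrap range of that test was added after its median was seen. The control pools form 1 group with no named difference between them. The explanations tested concern the tissue sampled, the cells in it and the table, and none concerns the hens' treatment or physiology.

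Lipid absorption genes were lowest in pool 3. Dilution of the epithelium by other tissue alone is argued against by 16 structural epithelial genes such as EPCAM and VIL1, whose median shift in pool 3 was -0.14 against -0.75, a difference of 0.61 with a bootstrap range over genes of 0.31 to 0.95. Some of these genes, such as EPCAM, VIL1 and CDH1, are in the fixed lists, so their shifts were already known. The test was thus only in part an independent check. The 16 genes were mixed, with shifts in pool 3 from -0.60 for SPINT1 to 0.76 for KRT18. The bootstrap range is over genes that can vary together, not over pools. A larger share of crypt against villus stays open, since the shift of crypt markers in pool 3, 0.50 and 0.15 without pool 1, was already known when the test was chosen, and most are cell cycle genes of other cells too. For a more distal stretch of intestine, 5 distal markers without FABP6 had a median of -0.29, the side that would count against it, but with a bootstrap range of -0.78 to 1.32, since SLC10A2 was higher in pool 3 and CUBN and AMN lower. All 9 proximal markers with a mean of at least 1 FPKM were lowest in pool 3, among them GATA4 at 29.71, 23.70 and 20.41 FPKM. Of these markers, APOA4, SLC2A2 and SLC2A5 are also in lists that were low there, and 16 of 17 brush border list genes were lowest in pool 3. The proximal markers thus cannot separate position from a general fall of enterocyte genes, and a more distal stretch stays open.

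Interferon stimulated genes were highest in pool 1. IFI6 was not alone in this, since 15 of the other 17 genes were highest in pool 1. The list without it lay at percentile 99.98. A median over members moves little without 1 gene, and 16 of 18 members were already known to be highest there. Leaving out IFI6 was therefore no independent check. For more immune cells in pool 1, the T and NK and the macrophage lists were not higher there, and the higher of their shifts was -0.30. The B and plasma cell list was at -0.26 and the heterophil and mast list at -0.06. These shifts were already known when the test was chosen, so it was no independent check and no conclusion is drawn from it. A higher share of epithelium in pool 1 stays open, since structural epithelial genes had a median shift of 0.14 there against 0.25 for the interferon list without IFI6.

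The deposited read counts did not follow the FPKM of their row. No constant offset between rows accounts for this, as the highest correlation over 15676 offsets was 0.030. The same values in another row order are argued against by FABP1, APOA1 and APOA4. If each transcript is at least 0.2 kb long and the summed counts are the library totals, as this explanation implies, the rows with enough counts had ratios between pools 3 and 1 at least 1.85 times those of the FPKM. Of 9435 rows with more than 100 counts in pool 1, 3204 shared all 3 counts with another row, against 2 of 8264 rows above 5 FPKM, and where the counts came from stays open.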
